A study of Mus musculus with 2 samples.

How the data were processed

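H3K9me3 chromatin immunoprecipitation followed by sequencing was done on forebrain of newborn mice (postnatal day 0), with 2 biological replicates in 1 group. Per the labels, fragments of 300 to 500 bp were selected, replicate 1 was a pool of 15 mice, and both pools were of mixed sex. The 4 deposited peak lists were used: replicate 1, replicate 2, the pooled alignments of both, and the replicated peaks. Per the submitters' read-me files, each list is on the mm10 assembly, the replicate lists and the pooled list were each called with the same further files, whose role is not stated, and the replicated list was derived from the other 3. The aligner, the peak caller, their versions and the calling threshold are not given in the sources used here.

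Each deposited peak came with a score scaled by the authors so that the strongest peaks have the highest values, with a fold enrichment (a ratio written by the authors' peak caller), and with the caller's −log10 p-value and −log10 q-value. The smallest deposited −log10 p was 2.04 in replicate 1, replicate 2 and the pooled list, and 2.16 in the replicated list. Deposited q-values under 0.05 were carried by 43.9% of replicate 1 peaks, 30.1% of replicate 2 peaks, 72.9% of pooled peaks and 97.5% of replicated peaks. These fold, p and q values belong to the peak in its own list, and were used only to rank or filter peaks within a list; the score was not used. No file gives read counts, so depth per sample is unknown and no value was scaled by it. Intervals on shares of peaks are Wilson 95% intervals and cover counting error only.

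From the peak positions, covered lengths, overlaps and gene cover were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9. The reference was GRCm38 with GENCODE M21, the same assembly as mm10. Positions are 1-based. The background of every gene test was all 21755 protein-coding genes on chromosomes 1 to 19 and X, each taken as its body with 1 kb upstream; genes were joined to peaks by position, and list members by symbol. Sequence outside these chromosomes was left out of every rotation, and Y was described separately.

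Overlap of the replicates was at least 1 bp, tested against rotation of 1 list by a random distance along each chromosome, with the first 3 Mb left out (100000 rotations, one-sided). Support of the replicated peaks required 50% of either interval. Genic location used peak midpoints and 10000 rotations (two-sided), with promoters within 1 kb of a transcription start. GC content, masked repeats and CpG observed over expected used 1000 rotations (two-sided). The 21 gene lists were compared with all genes by covered bp over summed span, with membership rotated along the gene order over every offset (two-sided). Adjusted p-values are Benjamini-Hochberg values within each family of tests. The cover of X was only ranked among 20 chromosomes. Uniqueness of sequence was the percent of a peak's 50-base words found once in the genome, with 90% taken as mostly unique.

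Comparisons, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named the 10 replicated peaks with the highest fold after keeping 1 per 100 kb, the 20 protein-coding genes with the most covered bp, up to 4 marked members per list with the largest covered share, and the 5 largest domains joined across gaps of up to 10 kb. Genes named outside the rule are said to be so where they appear, except that lists with few marked members are given in full and the further imprinted genes are named because they are marked. The alternatives fixed in advance were other overlap rules, a −log10 p of at least 5, equal numbers of strongest peaks, the pooled list, a 2 kb promoter window, gene cover within 1 kb of the transcription start, random genes matched on span in 10 classes, removal of the top 1% of peaks by fold, and each replicate left out. A replicate was left out by using the strongest peaks of the other, as many as there are replicated peaks. A gene with no peak in such a setting can still carry a weaker peak of the replicate kept. The comparison with genes matched on span counted marked genes, drew each gene singly and was not simulated. Neighbours that share a peak thus count as independent in it. Added after the data were seen were a count of each base pair once, a limit to peaks of mostly unique sequence, and a rotation of the peaks along the chromosomes in place of the gene order.

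The steps were tested on simulated data. For the gene lists, the null sets had 21755 genes and peaks rotated to break any relation to genes. Rotation of gene order gave p under 0.05 in 10.6% of 840 tests of a list, about double the nominal share. Rotation of the peaks gave 5%, but the null sets were made by the same rotation, so this share was fixed in advance. It does not show how that test behaves with real peaks. The excess under rotation of gene order was uneven: 0% for protocadherins, 12.5% for zinc finger genes, and 42.5% for the X-linked Rhox, Mage, Xlr and Slx list, each over 40 simulated sets. Keratins were at 35% and ribosomal protein genes at 30%. Under rotation of the peaks, imprinted genes were highest, at 15%. All 40 planted lists were found (100%), but their cover was 13.8-fold to 60.9-fold over all genes, above the main value of every real list but protocadherins, so the power for weaker lists was not tested. For the overlap of the replicates, 30.2% of 27906 peaks were planted as shared and 30.4% were found.

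With 2 replicates in 1 group, no test between samples was possible, and p-values describe position in this genome. Values of each replicate stand beside the main ones for that reason.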

Results

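Trimethylation of lysine 9 on histone H3 (H3K9me3) was mapped by chromatin immunoprecipitation and sequencing in the forebrain of mice at postnatal day 0. The series held 1 group with 2 biological replicates, each a pool of both sexes; replicate 1 pooled 15 mice, and the number in replicate 2 was not given in the sources used here. The question was where this mark of silent chromatin lies in the newborn forebrain, and no contrast between groups was possible. The authors deposited 4 peak lists on the mm10 genome: 28198 peaks for replicate 1, 27816 for replicate 2, 40031 for the pooled alignments, and 8853 replicated peaks drawn from the other lists. Replicate 1 covered 7.82 Mb with a median peak length of 226 bp, and replicate 2 covered 8.95 Mb with a median of 266 bp. Replicated peaks covered 4.89 Mb, with a median length of 449 bp and a median deposited fold enrichment of 3.43 (range 1.5 to 12.1). The read depth behind the peaks is unknown, because the files hold no read counts.

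H3K9me3 is a broad mark, and short peaks called within broad weak domains need not fall at the same bases in 2 libraries. Of the replicate 1 peaks, 7387 (26.2%) met a replicate 2 peak by at least 1 bp, and 7218 replicate 2 peaks (25.9%) met a replicate 1 peak. The shared sequence came to 1.89 Mb, 12.7% of the sequence covered by either replicate. On chromosomes 1 to 19 and X, 25.8% of replicate 1 peaks were shared against a mean of 0.707% after rotation of the peaks along each chromosome, a 36.4-fold excess (one-sided permutation p = 1e-05, the smallest that 100000 rotations can give). Sharing rose with peak strength. Among replicate 1 peaks with a deposited −log10 p of 2 to 4, 16.8% were shared, and among those of 10 or more, 416 of 478 (87.0%, Wilson 95% interval 83.7 to 89.7) were shared. The same classes of replicate 2 gave 16.0% and 331 of 360 (91.9%, interval 88.7 to 94.3). With both lists kept to a −log10 p of 5 or more, however, 20.5% of replicate 1 peaks and 28.5% of replicate 2 peaks were shared. Across the 7387 shared pairs, which are not independent replicates, fold enrichment in replicate 1 and replicate 2 had a Spearman rho of 0.206.

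**Figure D1:**
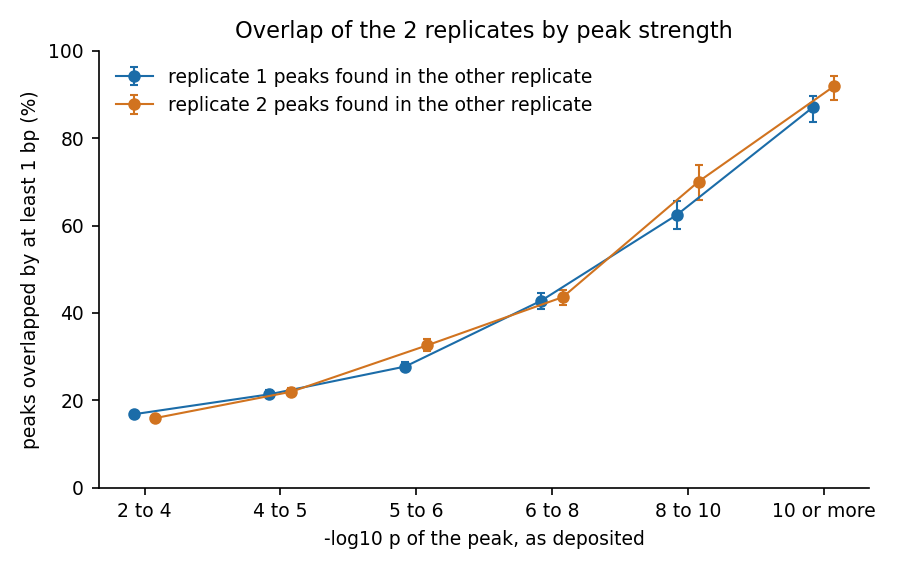
Percent of each replicate's peaks that met a peak of the other replicate by at least 1 bp, by the deposited −log10 p of the peak; bars are Wilson 95% intervals for counting error only. The share rose from 16.8% to 87.0% in replicate 1 and from 16.0% to 91.9% in replicate 2.

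All 8853 replicated peaks were identical in position to a peak of the pooled list, of which they made up 22.1%. With an overlap of at least 50% of either interval, 6691 of them (75.6%, Wilson 95% interval 74.7 to 76.5) met a peak in both replicates, 1177 in replicate 1 only, 947 in replicate 2 only, and 38 in neither. All 6691 pooled peaks that met both replicates in this way were in the replicated list. Overlap of replicated peaks with both replicates, here and below, may therefore follow from how the list was drawn, and is not independent support. Pooled peaks that were kept as replicated had a median fold enrichment of 3.43, against 2.73 for those that were not kept.

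Mouse chromosomes differ in how many gene clusters under H3K9me3 they carry, such as zinc finger, vomeronasal and protocadherin clusters. Chromosome 7 had the highest density of replicated peaks, 4635 bp per Mb, with 1248 peaks, which was 2.78 times the autosomal median of 1669 bp per Mb; in replicate 1 and replicate 2 taken alone, this ratio was 2.49 and 1.93. With as many of the strongest peaks of replicate 2 as there are replicated peaks (replicate 1 left out), 1 autosome was denser than chromosome 7. Chromosome 17 followed with 3549 bp per Mb, chromosome 18 with 3524, and chromosome 4 with 3146. Chromosome 14 was the lowest autosome, at 885 bp per Mb. On chromosome 18, a 0.912 Mb region from the first to the last clustered protocadherin gene, 1.01% of the chromosome, held 64.8% of the sequence under replicated peaks (48.7% in replicate 1 and 40.7% in replicate 2). This region was measured after the chromosome's value was seen.

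The X chromosome carried 70 replicated peaks and 294 bp per Mb, 0.176 of the autosomal median and the lowest of 20 chromosomes; this rank can give no exact one-sided p below 0.05. It was also the lowest in each replicate, at 1565 bp per Mb in replicate 1 and 429 in replicate 2. The ratio to the autosomal median was 0.111 with replicate 1 left out and 0.388 with replicate 2 left out. Replicate 1 had 1062 X peaks (3.81% of its peaks on chromosomes 1 to 19 and X) and replicate 2 had 230 (0.834%). Of the replicate 1 peaks, 5.65% of those on X were met by replicate 2, against 26.6% of those on autosomes. Of the replicate 2 peaks, 28.3% of those on X were met by replicate 1, against 25.4% of those on autosomes. The Y chromosome carried 4 replicated peaks.

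**Figure D2:**
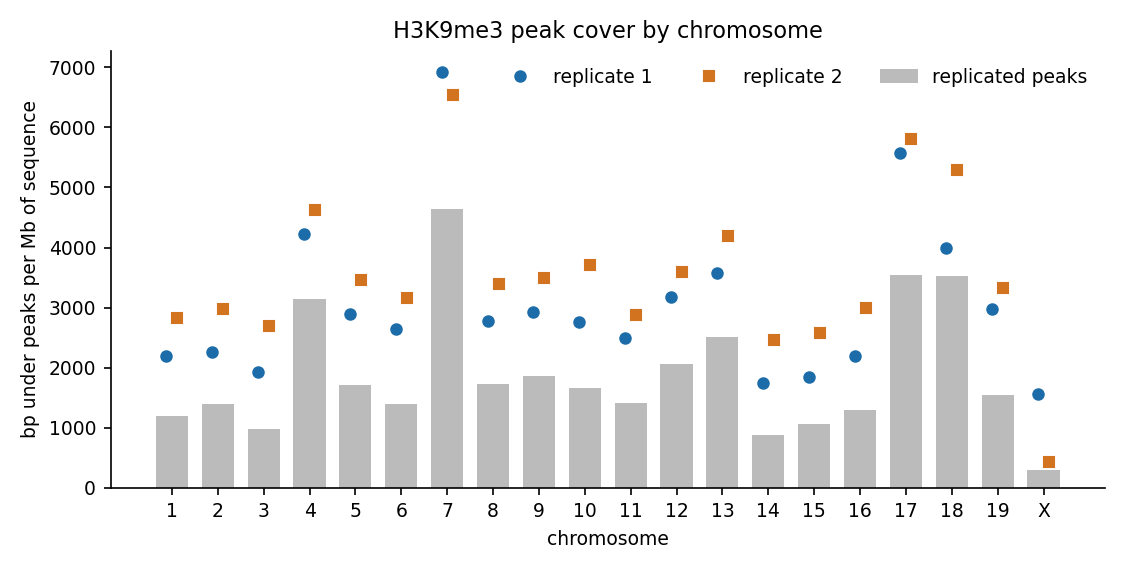
Base pairs under peaks per Mb of sequence on each chromosome, for the replicated list and for each replicate. Chromosome 7 was highest for replicated peaks at 4635 bp per Mb, and X was lower than any autosome in all 3 lists.

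Most replicated peaks lay outside genes. Of 8668 peak midpoints, 5580 (64.4%) lay between protein-coding genes, against 58.1% after rotation of the peaks, and 2260 (26.1%) lay in introns, against 35.9%. Exons held 542 midpoints (6.25% against 3.32%, a 1.89-fold excess). The exon and intron shares each had a two-sided permutation p of 0.0002, the smallest that 10000 rotations can give (adjusted 0.0004 over 4 locations), and the share between genes had an adjusted p of 0.0008. Within 1 kb of a transcription start lay 286 midpoints (3.30% against 2.73%, adjusted permutation p = 0.0784), a difference that did not pass the threshold and fell below the rotated share in the pooled list (2.48%). Exons held 4.61% of midpoints in replicate 1 and 4.12% in replicate 2, both above their rotated shares. Rotation also moves peaks into repeated sequence: 79.7% were mostly unique after 1 rotation, against 97.5% of replicated peaks. How far this shifted the shares by location was not tested.

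Sequence under replicated peaks had 44.3% GC, against 42.1% ± 0.332 (SD over 1000 rotations), and was rich in unique sequence. Repeats masked in the genome made up 23.2% of it, against 33.7% ± 0.893 (each permutation p = 0.002, the smallest possible; adjusted 0.003). Of 8674 replicated peaks on chromosomes, 97.5% had at least 90% of their 50-base words found once in the genome. After 1 rotation this held for 79.7% of 8639 peaks. The filtering of reads is not given, so the low share of repeats cannot be told apart from repeats where peaks could not be called. CpG observed over expected was 0.182, against 0.193 ± 0.00372 (permutation p = 0.00599), and the call was lost when either replicate's strongest peaks were used alone (0.187 and 0.188).

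The replicated peak with the highest fold enrichment of all covered Klf14, an imprinted single-exon gene. Its −log10 p was 55.3, below the highest of the replicated list, 149. The peak lay at chromosome 6, 30955589 to 30959674 (mm10), with a fold of 12.1. Next by fold among the 10 named peaks on chromosomes came a peak on chromosome 16 (3233617 to 3234697, fold 8.37), 356344 bp from Olfr161, and a peak on chromosome 7 (12013249 to 12014536, fold 7.68), 22215 bp from Vmn1r77. A peak on chromosome 13 (12927487 to 12929549, fold 7.62) lay 66575 bp from Prl2c2, and one on chromosome 18 (37746320 to 37750098, fold 7.51) covered the first exon of Pcdhga10, within the spans of several other protocadherin genes. A peak on chromosome 4 (146535860 to 146536639, fold 7.28) lay in an intron of Zfp981. The other 4 of the 10 lay on scaffolds, which the gene set did not cover, so no nearest gene can be given for them. Each of the 10 was met by a peak in both replicates.

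Some of the peaks lay in dense domains, though whether peaks cluster was not tested. Joined across gaps of up to 10 kb, the replicated peaks formed 5387 domains, of which 4357 held a single peak; the 82 domains with at least 10 peaks held 24.1% of the covered sequence. By covered length, ranks 1, 2 and 4 were all in the protocadherin clusters of chromosome 18. The Pcdhga and Pcdhgb domain (37656123 to 37774261) had 88970 bp covered (75.3%), the Pcdha domain (36898923 to 37062285) had 50737 bp (31.1%), and the domain from Pcdhb9 to Pcdhb22 (37403181 to 37542736) had 39954 bp (28.6%). Rank 3 was a 46898 bp domain on chromosome 1 (88211395 to 88258292) with 44131 bp covered (94.1%), over the shared end of the Ugt1a genes and Mroh2a. Rank 5, on chromosome 7 (17927788 to 18150464), had 39787 bp covered (17.9%) in 71 peaks around Ceacam11, Ceacam12 and Ceacam13. In replicate 1 and replicate 2 taken alone, peaks covered 71961 and 82482 bp of the first of these domains and 43064 and 39219 bp of the Ugt1a and Mroh2a domain.

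Clustered protocadherins are neuronal adhesion proteins, encoded in 3 neighbouring clusters on chromosome 18. Each Pcdha and Pcdhg gene has its own variable first exon and promoter, joined to constant exons, and a neuron expresses only a few of these exons. Of 57 members, 52 carried a replicated peak in the gene body or 1 kb upstream, and peaks covered 23.5% of their summed spans, against 0.324% for all 21755 protein-coding genes, a 72.5-fold ratio. The covered share was 19.7% in replicate 1 and 22.4% in replicate 2, and the mean fold of the replicates was 51.7 ± 0.656 (SD, n = 2). List membership rotated along the gene order, a two-sided permutation test, gave p = 0.00165 (adjusted 0.0348 over 21 lists, the only list to pass). The most covered members by share were Pcdhb19 (61.0%), Pcdhb17 (54.1%), Pcdhb20 (53.6%) and Pcdhga2 (48.5%). With replicate 1 left out these were 14.2%, 29.0%, 43.8% and 42.4%, and with replicate 2 left out 33.2%, 23.7%, 23.4% and 36.4%. By covered length, 16 of the 20 most covered genes in the genome were protocadherins, led by Pcdhga1 with 86975 bp (48.0%); 3 more, Gm42416, Gm37013 and Gm37388, are gene models that span the same clusters, and the last was Mroh2a. The spans of these protocadherins are nested, so the same base pairs count for several of them. These base pairs also count several times in the 0.324% for all genes, which raises that share and lowers the folds of the other lists.

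The 5 members without a replicated peak were Pcdhac2, Pcdhb12, Pcdhgc3, Pcdhgc4 and Pcdhgc5, named after their values were seen. Of these, 4 are of the C type, the last variable exons of the Pcdha and Pcdhg clusters, which are expressed by most neurons rather than chosen by a few. A split by kind, chosen after these names were seen, was therefore made on the first annotated exon of each gene. Replicated peaks marked the first exon of all 12 Pcdha genes (61.0% of its sequence), 21 of 22 Pcdhb genes (32.4%) and all 18 Pcdhga and Pcdhgb genes (89.4%), but of 0 of the 5 C-type genes. Of the C-type genes only Pcdhac1 carried a replicated peak elsewhere in its span. The first exons of the C-type genes were also free of peaks in replicate 1 and in replicate 2, where those of Pcdhga and Pcdhgb were covered over 80.0% and 83.1%. No test of the split is given, because the unmarked genes prompted it.

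**Figure D3:**
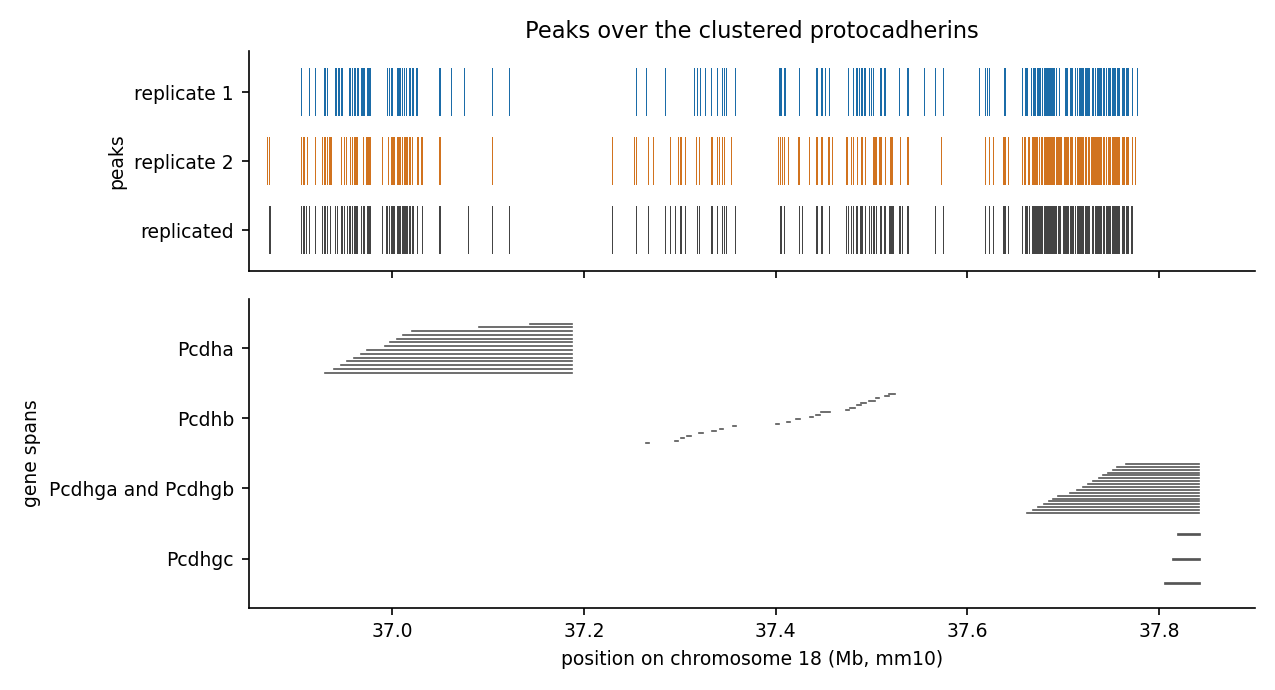
Map of the clustered protocadherin region of chromosome 18 (mm10 position in Mb), with the gene spans and the peaks of replicate 1, replicate 2 and the replicated list. The Pcdhga and Pcdhgb domain was covered over 75.3%, the Pcdha domain over 31.1% and the domain from Pcdhb9 to Pcdhb22 over 28.6%.

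Zinc finger genes with Zfp symbols include the large family of Krüppel-type repressors, many of which stand in tandem arrays and are themselves packed in H3K9me3. Of 460 such genes, 113 (24.6%) carried a replicated peak, against 7.40% of all protein-coding genes. Peaks covered 2.01% of their spans, a 6.20-fold ratio to all genes (1.75% in replicate 1 and 2.19% in replicate 2), which reversed to 0.335 when only 1 kb either side of the transcription start was used. In the planned rotation of gene order the list did not pass (permutation p = 0.0302, adjusted 0.156). Rotating the peaks along the chromosomes, a test added after the data were seen, gave an 8.27-fold excess (permutation p = 0.0002, the smallest possible; adjusted 0.0042). Zfp873 was the most covered member, at 69.5% of its span (50.8% in replicate 1 and 63.5% in replicate 2), followed by Zfp110 (65.1%), Zfp68 (55.4%) and Zfp2 (45.7%). With replicate 2 left out these fell to 39.2%, 31.6%, 24.2% and 26.4%. Chromosome 9 had the largest marked share among chromosomes with at least 20 such genes, 13 of 23 (56.5%), followed by chromosome 13 with 16 of 43 (37.2%). Chromosome 7, with the most Zfp genes, had 23 of 106 marked (21.7%), below the share of the whole list.

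Cytochrome P450 and UDP-glucuronosyltransferase genes act mainly in liver and gut. Peaks covered 2.63% of the spans of 96 such genes, an 8.11-fold ratio to all genes (2.85% in replicate 1 and 2.65% in replicate 2), with 16 marked. The planned test did not pass (permutation p = 0.0371, adjusted 0.156), whereas rotation of the peaks gave 12.4-fold (adjusted 0.0210). With each base pair counted once, the list fell to 4.44-fold and 0.772% covered, with 9 genes marked, and did not pass (adjusted permutation p = 0.127). The list's cover was concentrated at 1 locus: 9 of the 16 marked genes were Ugt1a genes, which share their last exons. Ugt1a1 was covered over 90.9% of its span, and Ugt1a2 and Ugt1a5, which contain the same sequence, over 37.7% and 15.4%; Cyp3a11 on chromosome 5 was covered over 10.3% (3.52% with replicate 1 left out and 2.07% with replicate 2 left out). The adjoining Mroh2a was covered over 31720 of 36304 bp (87.4%; 87.1% in replicate 1 and 76.6% in replicate 2). Trpm8, the next gene, which was chosen after its value was seen, was covered over 24197 bp (21.5%).

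**Figure D4:**
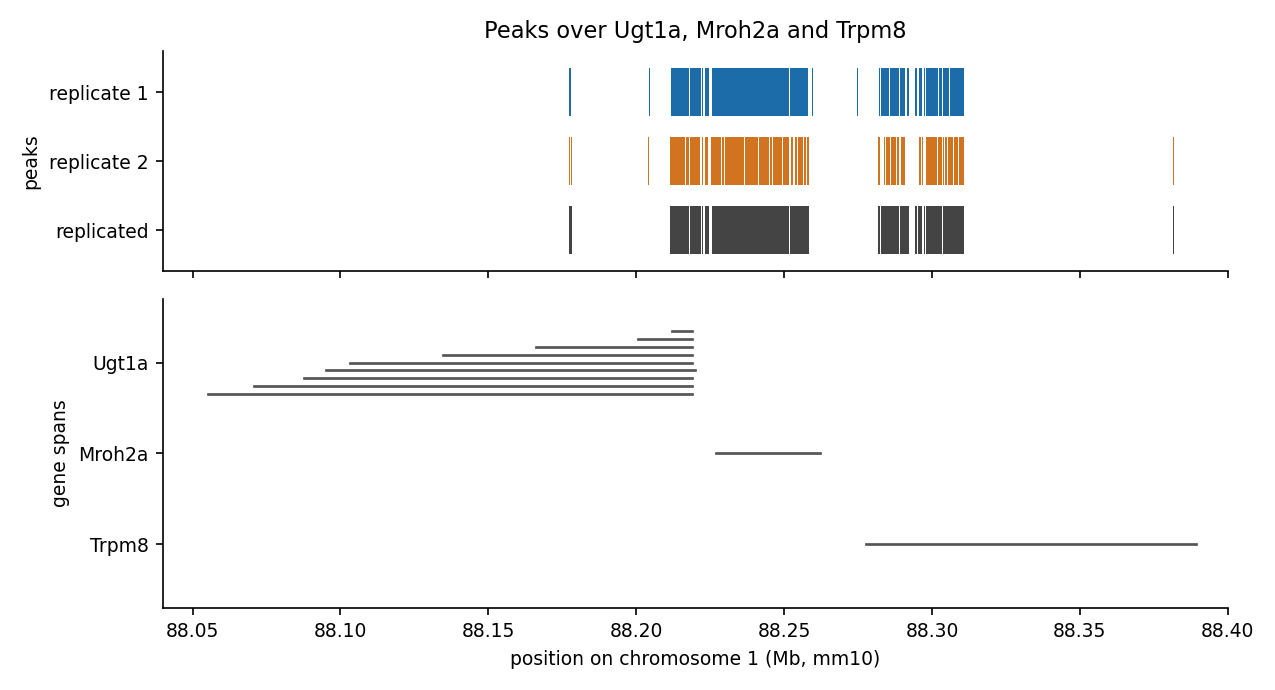
Map of the Ugt1a, Mroh2a and Trpm8 genes on chromosome 1 (mm10 position in Mb), with the peaks of replicate 1, replicate 2 and the replicated list. The domain over the shared end of the Ugt1a genes and Mroh2a had 94.1% of its 46898 bp covered.

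Imprinted genes carry regulatory regions that are DNA-methylated and marked by H3K9me3 on a single parental copy. Of 59 such genes, 26 carried a replicated peak, and peaks covered 0.985% of their spans, 3.04-fold over all genes (1.06% in replicate 1 and 1.08% in replicate 2). Neither the planned test (adjusted permutation p = 0.196) nor the rotation of peaks (3.78-fold, adjusted p = 0.157) passed. The planned count of marked genes against random genes matched on span did pass (4.40-fold, adjusted permutation p = 0.00105). That count draws genes singly, although some imprinted neighbours share a peak. Klf14 was covered over 90.04% of its span, Nap1l5 over 53.3%, Cdkn1c over 29.7% and Mkrn3 over 20.0%. With replicate 1 left out these were 87.9%, 34.5%, 0% and 6.34%, and with replicate 2 left out 52.0%, 8.30%, 12.1% and 18.5%. In the full replicate 2 list, Cdkn1c was covered over 12.5%. The other marked genes, which the rule for naming genes does not include, were Gpr1, Zdbf2, Blcap, Nnat, Gnas, Peg10, Mest, Herc3, Peg3, Usp29, Ube3a, Snrpn, Snurf, Ndn, Inpp5f, Kcnq1, Plagl1, Grb10, Trappc9, Slc22a2, Igf2r and Impact.

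Chemosensory receptor genes are silent in the brain and stand in large arrays. Vomeronasal receptors were marked at 49 of 327 genes (2.61-fold, adjusted permutation p = 0.196), led by Vmn1r82 (22.1%), Vmn1r71 (15.8%), Vmn1r76 (13.6%) and Vmn1r83 (10.4%), all on chromosome 7. The fold was 1.57 with replicate 1 left out. In the count of marked genes against random genes matched on span, the list passed (3.97-fold, adjusted permutation p = 0.00105). That count draws genes singly and ignores their arrays. With replicate 1 left out the named vomeronasal genes were at 11.9%, 5.35%, 0% and 2.64%, and with replicate 2 left out at 0%, 8.92%, 6.32% and 3.61%. In the full lists Vmn1r82 was covered over 14.2% in replicate 1 and Vmn1r76 over 7.25% in replicate 2. Olfactory receptors were marked at 42 of 1094 genes (0.850-fold, adjusted permutation p = 0.457, but above all genes in each replicate alone, at 1.81-fold and 1.39-fold), led by Olfr849 (17.5%), Olfr355 (16.1%), Olfr50 (14.9%) and Olfr399 (13.7%). In the same count of marked genes, which is not a covered share, the olfactory list was above random genes and passed (1.53-fold, adjusted permutation p = 0.0280). With replicate 1 left out the named olfactory genes were at 3.36%, 0%, 3.44% and 0%, and with replicate 2 left out at 7.27%, 20.2%, 3.97% and 4.97%. In the full replicate 2 list Olfr355 was covered over 14.9% and Olfr399 over 7.42%. Bitter taste and trace amine receptors were marked at 3 of 50 genes (3.99-fold, adjusted permutation p = 0.172): Tas2r107, Tas2r105 and Tas2r120 on chromosome 6. All 3 had no peak among the strongest kept with replicate 2 left out, where the list was at 2.42-fold. Tas2r105 also had none with replicate 1 left out or at −log10 p of 5 or more. In the full replicate 1 list the 3 genes were covered over 8.81%, 34.0% and 19.7%. Tas2r105 was covered over 14.8% in the full replicate 2 list. Defensins were marked at 3 of 64 genes (2.38-fold, adjusted permutation p = 0.199): Defb33, Defb4 and Defb8, all on chromosome 8. The list reversed to 0.735-fold with replicate 1 left out and 0.440-fold with replicate 2 left out. Among the strongest peaks kept with either replicate left out, Defb4 had none and Defb33 fell from 24.1% to 4.38% or 4.41%. Defb8 had none with replicate 2 left out. In the full lists of replicate 1 and replicate 2, Defb33 was covered over 20.3% and 23.3% and Defb4 over 5.44% and 6.46%. Defb8 was covered over 15.8% in the full replicate 1 list.

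Genes active in the forebrain and genes silent in it were compared with all genes in the same way. Neuronal genes had a peak at 7 of 40 members, Snap25, Reln, Grin2b, Syt1, Nrxn3, Nefm and Nrxn1, a share of 17.5% against 7.40% of all genes, but these genes are long and 0.0383% of their spans was covered, 0.118 of the value for all genes (0.264 with replicate 1 left out and 0.1198 with replicate 2 left out). The highest was Nefm, at 1.56% (0.839% with replicate 2 left out). The planned test did not pass (adjusted permutation p = 0.409), the rotation of peaks gave 0.208-fold (adjusted p = 0.0493), and the marked genes numbered 1.03 times those among genes matched on span (adjusted p = 1). No replicated peak lay in 45 forebrain patterning and progenitor genes, 20 glial genes, 79 ribosomal protein genes (adjusted permutation p = 0.0531), 69 histone genes, 106 keratins (adjusted p = 0.125), 32 major urinary proteins and lipocalins, or 70 Rhox, Mage, Xlr and Slx genes of the X chromosome. None of these passed the planned test. A cover of 0 arose in 3.42% of rotations of the peaks for forebrain patterning genes (permutation p = 0.0686, adjusted 0.160), 22% for glial genes, 22.4% for ribosomal protein genes, 33.1% for keratins, 46.4% for the X-linked list, 60.2% for histone genes and 62% for major urinary proteins and lipocalins. Patterning genes were at 0.397-fold and 0.0567-fold with replicate 1 and replicate 2 left out, and glial genes at 0.301-fold and the X-linked list at 0.162-fold with replicate 2 left out. The 39 Hox genes, held by Polycomb rather than H3K9me3 in most tissues, also had none, although 11 carried a replicate 1 peak and 16 a replicate 2 peak. Their cover in each replicate alone was above that of all genes, at 2.85-fold in replicate 1 and 3.57-fold in replicate 2.

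Germline genes had a replicated peak at 8 of 76 members (0.539-fold, adjusted permutation p = 0.802), the most covered being Tdrd6 (9.28%), Dazl (7.66%), Meioc (3.17%) and Syce3 (2.23%). With replicate 1 left out these were 5.16%, 0%, 5.51% and 3.42%, and with replicate 2 left out 6.70%, 1.63%, 1.46% and 1.60%. In the full replicate 2 list, Dazl was covered over 5.89%. In the blood, vessel and microglia list only Tek was marked by a replicated peak, 1 of 33 (0.115-fold, adjusted permutation p = 0.457). The list was at 0.396-fold with 2 genes marked when replicate 1 was left out, and at 0.290-fold with 3 when replicate 2 was left out. Genes of non-neural organs had Cyp3a11 and Ckm marked, 2 of 53 (1.28-fold, adjusted permutation p = 0.409), and were at 0.631-fold and 0.643-fold with replicate 1 and replicate 2 left out. Among 26 genes of the H3K9 methylation machinery itself, Atf7ip (2.18%), Fam208a (0.714%) and Smchd1 (0.281%) were marked (0.622-fold, adjusted permutation p = 0.580); Atf7ip fell to 0.735% and 0.841% with replicate 1 and replicate 2 left out, and Fam208a had no peak in the latter case. The fold of this list was 0.383 and 0.375 in these settings. In the full replicate 1 list, Fam208a was covered over 0.461%. All p-values over genes describe position in this genome, not variation between animals, and the direction of the olfactory, Hox, germline, neuronal, defensin, non-neural organ and methylation machinery lists changed under at least 1 other setting.

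**Figure D5:**
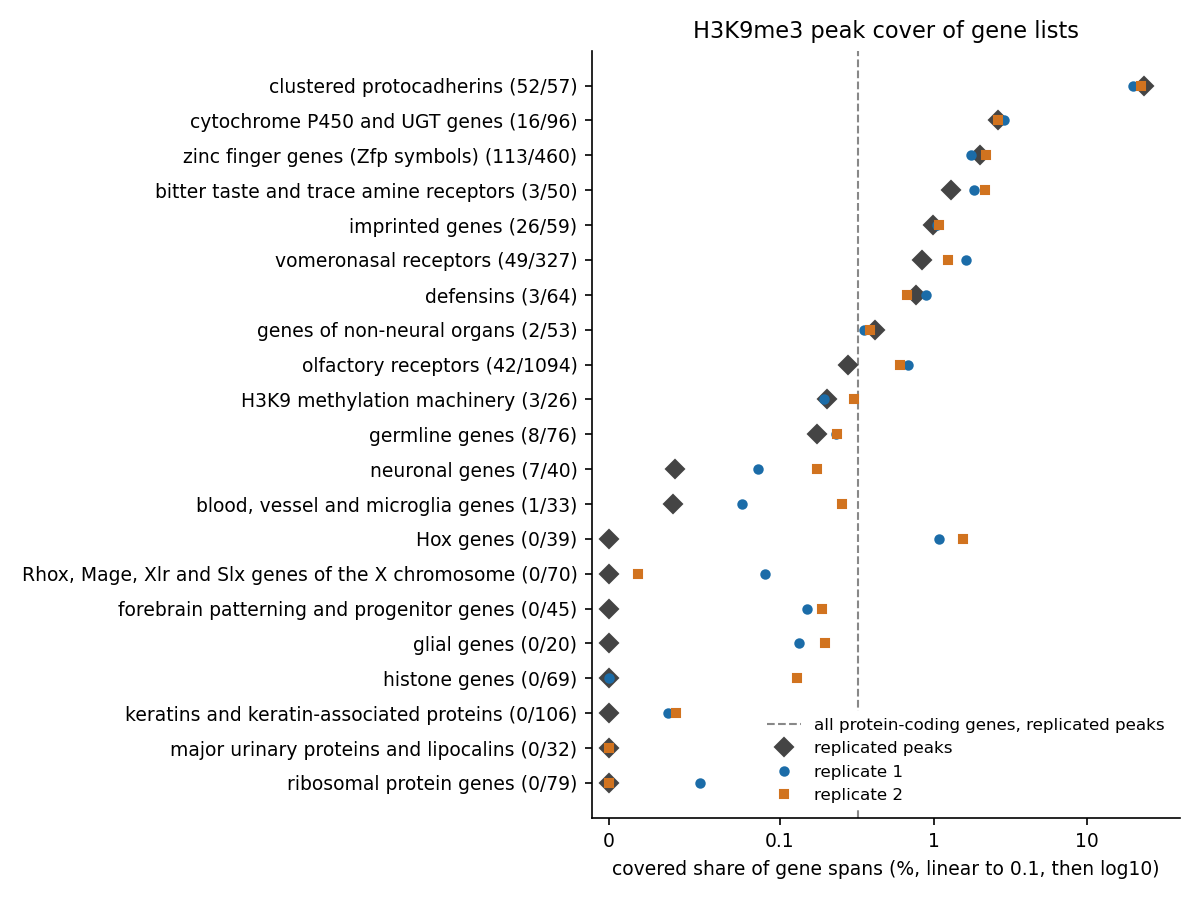
Percent of the summed gene spans (gene body with 1 kb upstream) under peaks for each of 21 gene lists, on a scale that is linear to 0.1 and log10 above; the numbers beside each list are the genes with a replicated peak and the members. Clustered protocadherins, at 23.5%, lay farthest from the line for all protein-coding genes at 0.324%.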

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

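The comparison by peak strength was chosen only after the share of peaks found in both replicates was seen, and the settings with only peaks of mostly unique sequence and with each base pair counted once were added after the data were seen.

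Of the replicated peaks, 179 (2.02%) lay on 16 scaffolds outside chromosomes 1 to 19, X and Y, sequence that the comparisons by position did not use. They included 49 of the 100 strongest replicated peaks by deposited p and covered 170 kb. Their median fold was 3.76, against 3.43 on chromosomes; 177 met a peak in replicate 1 and 163 in replicate 2. There was no control sample among the files, and no explanation was tested.

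Replicate 1 had 1062 peaks on X and replicate 2 had 230, and the share of peaks on X differed 4.56-fold (3.81% against 0.834%). Reads shared between repeated sequence are a candidate explanation. Of the X peaks that replicate 2 lacked, 98.3% were of mostly unique sequence, the same as for autosomal peaks that it lacked. Both medians were 100%. In the full lists, 98.1% of replicate 1 peaks and 97.9% of replicate 2 peaks were mostly unique, also with medians of 100%. The comparison of X with autosomal peaks thus had little room to differ and cannot decide on this explanation. It shows only that few of these X peaks lay in repeated sequence by this measure. If the further files listed for both replicates are controls, which is not stated, uneven X copy number in the mixed-sex pools might raise weak X peaks in 1 pool. Among peaks with −log10 p of 8 or more the ratio was 1.51, just over the bound of 1.5 set for that explanation (25 and 11 X peaks, Fisher's exact p = 0.304), but it was 3.27 from 6 or more (88 and 26) and 2.48 from 10 or more (16 and 5), and the strong peaks were too few to decide. No biological explanation was tested, and the sex ratio of the pools is not given in the sources used here.

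Clustered protocadherins and zinc finger genes carried a high peak cover. Reads shared between similar gene copies are a candidate explanation. With only peaks of mostly unique sequence, the fold over all genes was 73.0 for protocadherins and 6.09 for zinc finger genes. With all replicated peaks it was 72.5 and 6.20. The filter kept 97.5% of replicated peaks on chromosomes, so the folds had little room to move. A word counts as found once even where a similar copy differs from it slightly. Reads shared between such copies were therefore not examined, and the filter cannot decide on this explanation. Overlapping gene models count the same peak for many protocadherins. With each base pair given to the first gene in order that holds it, the fold was 100.1. Only 1 member stayed marked, with 17.4% of the list covered, because most of the region went to Pcdha1 and to Gm42416, outside the list. This setting therefore cannot decide whether multiple counting raised the fold. Without gene models, replicated peaks covered 200 kb of the 0.912 Mb protocadherin region. What the authors' filtering of reads did in these clusters remains open, since the steps are not given. No biological explanation was tested, as the series has 1 group.

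The share of peaks found in both replicates was low, at 26.2% of replicate 1 peaks. Weak peaks near the calling threshold are a candidate explanation, on which the tables go both ways. Of replicate 1 peaks with −log10 p of 10 or more, 87.0% were met in replicate 2, against 16.8% of those from 2 to 4. With weak peaks removed from both lists the share did not rise throughout: it was 20.5% and 28.5% at −log10 p of 5 or more, and 24.7% and 24.2% with equal numbers of strongest peaks, against 26.2% and 25.9% with all peaks. Longer strong peaks (median 619 bp against 204 bp) and a difference in depth remain open, and no biological explanation was tested.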

How the results depend on the processing

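The settings "each base pair once", "unique peaks" and "peaks rotated" were chosen after the data were seen; the other settings were planned. No paired analysis was possible because there is 1 group, and with depth unknown and 2 replicates, a replicate left out gives a range and no test between animals. Of 61 alternatives to the results other than single lists and genes, 46 kept direction and call. The X stayed lowest and exons stayed enriched in all settings run for them. Of 248 alternatives for the named genes, 115 stayed within the spread of the replicates; of 62 named genes, 7 lost every peak without replicate 1 and 7 without replicate 2, and 45 changed by over 1.5 times in at least 1 of these settings. Leaving a replicate out keeps only the strongest peaks of the other, so a gene that lost every peak can still carry a weaker one. Protocadherins kept direction and call in all their settings, although only 1 member stayed marked with each base pair once.

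Support of the replicated peaks was 77.2% at −log10 p of 5 or more and 43.7% with 50% of both intervals, a stricter rule by construction. The chromosome 7 ratio was 2.36 in the pooled list and 1.93 to 2.73 with a replicate left out; without replicate 1, 1 autosome was denser than chromosome 7. Promoters held 3.45% at −log10 p of 5 or more (now past the threshold), 2.48% in the pooled list (reversed) and 2.96% to 3.57% with a replicate left out, past it without replicate 2. CpG observed over expected was 0.187 to 0.188 with a replicate left out, no longer past the threshold. Lists passing numbered 1 in the main setting, 2 with each base pair once, 4 with peaks rotated, 3 in the pooled list, 6 with matched genes, and 2 without either replicate. Zinc finger genes passed at 11.9-fold with each base pair once, 8.27 with peaks rotated and 4.29 with matched genes, and reversed at 0.335 within 1 kb of the start.

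Among the 210 alternatives to single lists, 175 kept direction and call, 12 gained a call and 23 reversed. Besides zinc finger genes, calls were gained with matched genes by imprinted genes, vomeronasal receptors and cytochrome P450 and UGT genes, with peaks rotated by the latter and by neuronal genes, in the pooled list by keratins and ribosomal protein genes, and by the latter without either replicate. The gene-order test behind the keratin and ribosomal calls gave p under 0.05 in 35% and 30% of simulated null sets of these lists. The setting with matched genes draws genes singly and was not simulated. Within 1 kb of the start, methylation machinery was at 2.17 and germline genes at 4.66. With each base pair once, methylation machinery was at 1.17 and olfactory receptors at 1.57, although their covered shares hardly changed (0.202% to 0.204% and 0.276% to 0.273%). These 2 folds rose because the share of all genes fell once overlapping genes were no longer counted several times. With peaks rotated, methylation machinery and olfactory receptors were at 1.04 and 1.20, and germline genes at 1.06. In the pooled list, Hox genes were at 3.94, olfactory receptors at 1.89 and non-neural organ genes at 0.969. With matched genes, methylation machinery was at 1.09, germline genes at 1.36, neuronal genes at 1.03 and olfactory receptors at 1.53, past the threshold. Without the top 1% of peaks, olfactory receptors were at 1.03. With a replicate left out, Hox genes ranged from 1.09 to 1.39, defensins from 0.440 to 0.735, non-neural organ genes from 0.631 to 0.643 and olfactory receptors from 0.590 to 1.03. Apart from the rise of folds with each base pair once, the cause was not tested for any of these.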

Other observations

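The tests in this part were chosen after the data were seen, except the planned comparison of imprinted genes with other genes within 1 kb of each gene's start.

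Peaks in zinc finger genes lay toward the end of the gene, where the zinc finger exon of this family usually stands. Over 460 genes, replicated peaks covered 0.599% of the first 20% of the gene body and 6.89% of the last 20%, an 11.5-fold ratio. More was covered at the end in 79 genes and at the start in 9 (two-sided permutation of signs, p = 1e-05, the smallest that 100000 changes can give). This test takes genes as independent, although many stand in tandem arrays, so its p-value may be too small. Replicate 1 gave 0.605% and 5.58%, and replicate 2 gave 0.839% and 7.23%. With only peaks of mostly unique sequence, the values were 0.588% and 6.80%. Exons of zinc finger genes were covered over 6.18% and introns over 1.298%. The values were 0.356% and 0.124% in 21238 other protein-coding genes, a set without the clustered protocadherins.

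Some imprinted genes carried peaks at their starts. A replicated peak lay within 1 kb of an annotated transcript start in 17 of 59 imprinted genes (28.8%), against 300 of 21669 other symbols (1.38%). The covered share of these windows was 16.4 times that of rotated peaks (two-sided permutation p = 0.0002, the smallest that 10000 rotations can give), although this kind of rotation gave p under 0.05 in 15% of simulated null sets of the whole spans of these genes. The count over all annotated starts was not matched for the number of starts per gene. The planned setting of 1 kb either side of each gene's start marked 9 of the 59 genes. Against other genes, it gave 19.16-fold in the gene-order permutation and did not pass (adjusted p = 0.0724). The 17 genes with a peak at any annotated start were Blcap and Nnat (1 shared peak), Cdkn1c, Gnas, Grb10, Herc3 and Nap1l5 (1 shared peak), Impact, Inpp5f, Klf14, Mest, Mkrn3, Peg3 and Usp29 (1 shared peak), Plagl1, and Snrpn and Snurf (1 shared peak), 13 distinct peaks in all. The peaks of 15 of the 17 genes were met in both replicates; that of Snrpn and Snurf was not met in replicate 2. Apart from Klf14, with a fold of 12.1, their folds ranged from 2.94 at Plagl1 to 4.44 at Nap1l5. Of 9 imprinted non-coding genes, Airn, Meg3, Peg13 and Nespas carried such a peak, and H19, Kcnq1ot1, Rian, Mirg and Snhg14 did not.

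Cover was also compared with rotated peaks by gene type. It was 2.97-fold for unprocessed pseudogenes, 2.48-fold for processed pseudogenes and 1.72-fold for protein-coding genes (each adjusted permutation p = 0.0240 over 9 gene types), and 1.17-fold for long intergenic RNA genes (adjusted p = 0.543). Base pairs inside several genes of a type counted once for each gene, so the nested protocadherin spans weigh on the protein-coding value. By midpoints, introns held 26.1% of replicated peaks against 35.9% after rotation, and exons 6.25% against 3.32%. The 1.72-fold value therefore does not show that protein-coding gene bodies, each base pair taken once, were enriched. The differences between types were not tested, nor was the place of pseudogenes inside marked gene clusters. Here genes were taken without the 1 kb upstream. A replicated peak was carried by 4.27% of unprocessed and 1.02% of processed pseudogenes, 7.27% of protein-coding genes and 5.01% of long intergenic RNA genes. Of 239 further gene families grouped by symbol stem, 0 passed after adjustment and 11 had an unadjusted p under 0.05 in the rotation of peaks.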
